A study of Homo sapiens with 12 samples.

How the data were processed

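RNA was sequenced from the acute myeloid leukemia cell line MOLM-13 in 4 groups of 3 libraries: untreated control, venetoclax (labelled ABT-199, 500 nM for 1 h), CUDC-907 (25 nM for 10 h) and the combination (CUDC-907 for 10 h and ABT-199 for 1 h). The labels gave no doses for the combination and no vehicle for the control. Total RNA went into a strand-marking library kit (NEBNext Ultra II Directional) and was read as 150 bp pairs on an Illumina HiSeq. The deposited processed file, used as it stood, held for each gene and library a read count and a log2 value. Per the submitters' processing notes, cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1 and edgeR (version not stated) were used with the hg19 genome. The notes did not state the annotation, the strand setting of the counting, or any filter. The file marked each listed gene as protein-coding.

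The counts in the deposited file were whole numbers per the file headers, made by the authors from aligned reads, and all tests used them. The deposited log2 columns equalled edgeR log2 CPM with trimmed-mean (TMM) scaling and a prior count of 0.25, with a largest difference of 5.15e-14, and were not tested. The file listed 20307 genes, of which 5019 had 0 counts in all 12 libraries. A single line had been emptied for this work and was left out. Symbols were shared by more than 1 identifier in 74 cases, so genes were followed by Ensembl identifier. Library totals ran from 833122 to 1729936 counts. In the file the CUDC-907 columns carried the spelling CUDU and were taken as the labelled CUDC-907 samples.

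Genes were kept by the edgeR filterByExpr default for the 4 groups, which left 7870. All 12 libraries were fitted together in edgeR 4.0.16 under R 4.3.3 with TMM scaling, estimated dispersions (common dispersion 0.0479) and robust quasi-likelihood F tests. Adjusted p values were Benjamini-Hochberg values over the tested genes of each comparison, with a bound of 0.05. Comparisons were venetoclax, CUDC-907 and combination against control, combination against each single drug, and the interaction, which asked whether the change with both drugs differed from the sum of the single-drug changes. Standard errors (SE) were the absolute log2 fold change divided by the root of the F statistic. CPM (counts scaled to 1e6 per library with TMM factors) were given as mean and SD of 3 libraries. Where a group had 0 counts, a fold was given as a lower bound with 3 counts set over the group. Where it had 1 to 3 counts, the ratio of counts was given with a 95% interval that covers counting error only. The interval says nothing about spread between cultures.

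Before the data were examined, 33 gene lists were written for drug targets, metabolism, growth, stress, cell cycle, apoptosis, differentiation and lineage markers, and each is named once in the results with its test. Lists with at least 3 tested members were tested with limma 3.58.1 camera on voom values with the preset correlation of 0.01, adjusted over the 33 lists. The comparisons, the test, the bounds, the lists and the alternatives named next were also chosen before the data were examined. Alternatives were DESeq2 1.42.0 size factors, library totals as scaling, no low-count filter, at least 1 CPM in 3 libraries, DESeq2 Wald tests, limma-voom, only the groups compared, a replicate block, a 2-fold bound, leaving out each library, camera with an estimated correlation, and fry. A planned change of pseudocount was not applicable to counts. After the data were seen, tests restricted to genes clear of opposite-strand exons, scaling on those genes, library totals for the lists, and fits without combination replicate 3 in comparisons that do not use it were added.

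Exons on the opposite strand were taken from GENCODE release 29 by identifier, which matched 19498 of the listed genes and left 809 unmatched. Of the tested genes, 4000 had exons opposite another gene, 3729 were clear and 141 were unmatched. A gene is said to lie opposite another when their exons share bases on opposite strands. The locus columns of the file join overlapping genes, so the spans printed can be wider than the gene.

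Genes were named by rule. In each comparison these were the 10 largest called changes in each direction among genes with a mean of at least 8 CPM and groups that did not overlap, then up to 4 called members per list with the largest changes plus the largest of each direction, and 25 drug-target, apoptosis and leukemia genes chosen before the data were examined. The choice of CHEK1 and WEE1, and of the list of checkpoint and repair genes, drew on recalled published work on CUDC-907, not on any file here. Any gene outside the rule is said to be so where it is named.

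The fits were tested on simulated data with 50 genes changed at each fold. For venetoclax against control, 4, 15, 29 and 39 genes were recovered at 1.5, 2, 3 and 4-fold, and for CUDC-907 against control 5, 18, 36 and 34. For combination against CUDC-907 the numbers were 5, 23, 33 and 42, and for the interaction 1, 6, 20 and 23. False calls numbered 4, 2, 6 and 2 among 7461, 7495, 7455 and 7486 genes. Camera recovered the raised list in each of the 4 simulations and called 0, 0, 1 and 0 of 30 unchanged lists. Genes were simulated independently, so these lists held no correlation between genes. The simulations therefore do not measure how often camera calls an unchanged list of correlated genes. List calls in other splits of the real libraries are given at the end.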

Results

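The 12 MOLM-13 libraries were compared as counts of 20307 genes marked protein-coding in the file, with n = 3 libraries in each of 4 groups. Control libraries held 1011721, 1574686 and 1096588 counts, and venetoclax libraries held 1331832, 833122 and 1397602. CUDC-907 libraries held 1301723, 1346690 and 1601280 counts, and combination libraries held 1532971, 1729936 and 1413949. A mean of 10631 genes (SD 250) had counts in control libraries and 10538 (SD 357) in venetoclax libraries. After CUDC-907 the mean was 12073 (SD 306), and after the combination it was 12619 (SD 235). All 6 libraries treated with CUDC-907 lay above all 6 others (exact permutation p = 0.0022, 924 splits), while 3 against 3 libraries cannot give an exact p below 0.1. Nothing in the labels says that replicates came from separate cultures, so every p value measures only the spread between these samples. Combination replicate 3 stood apart from its group, with a TMM factor of 1.20 and a mean correlation of 0.935 with its group.

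**Figure D1:**
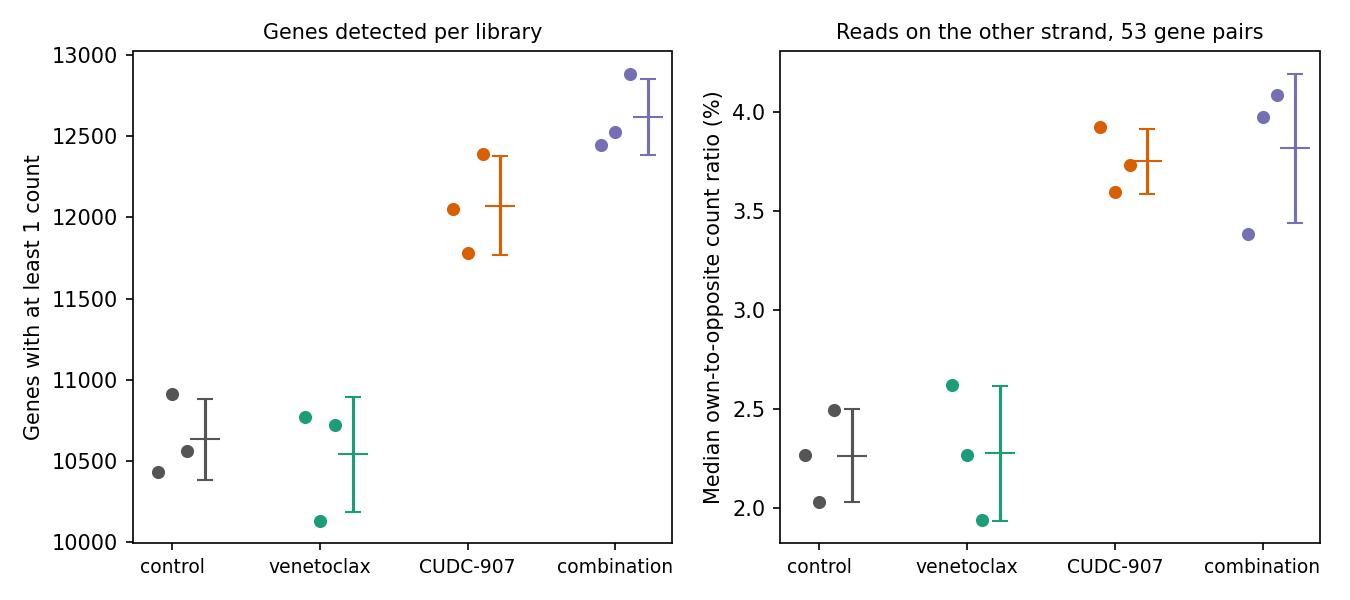
Genes with at least 1 count per library (left) and the median percent of own-strand to opposite-strand counts over 53 gene pairs (right) in the 4 groups. Pairs were kept only where the opposite gene held over 20 times the counts. Points are libraries and bars are mean and SD, n = 3. The 6 libraries with CUDC-907 lie above the others in both panels.

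Many of the highest counts belonged to genes with exons opposite another gene. Such genes made up 15 of the 20 highest, 406 of the 500 highest (81.2%) and 34.3% of all matched genes. ATG10, an autophagy gene, held 42536 CPM and lies opposite RPS23, a ribosomal protein gene with 384 CPM. BEST1, an ion channel gene, held 36550 CPM and lies opposite FTH1, the ferritin heavy chain gene, with 419 CPM. SH3D19 (26673 CPM) lies opposite RPS3A (224 CPM), and ENO3 (14519 CPM) lies opposite PFN1 (595 CPM). Of the 13 mitochondrial mRNAs, MT-ATP6, MT-ND4L, MT-CO2, MT-ND1, MT-ND4, MT-ND3 and MT-ATP8 had 0 counts in every library and MT-CO1 had 0 to 2. MT-ND6, encoded on the other mitochondrial strand, held 28606 CPM. For a gene named with a gene opposite it, the counts alone do not show which strand's transcript was read. The strand setting is not stated, so this limit also holds for genes clear of opposite-strand exons, such as MYC, BCL2 and CHEK1. If reads were counted on the opposite strand, counts of such genes would be the small share read from the other strand. Own-strand counts were 2.26% (SD 0.234) of opposite-strand counts over 53 pairs in control and 3.75% (SD 0.165) after CUDC-907. Own-strand here names the gene with fewer counts in each pair. Pairs were kept only where the other gene held over 20 times its counts, so a low percent was fixed by that choice. The difference between groups was not fixed by it.

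**Figure D2:**
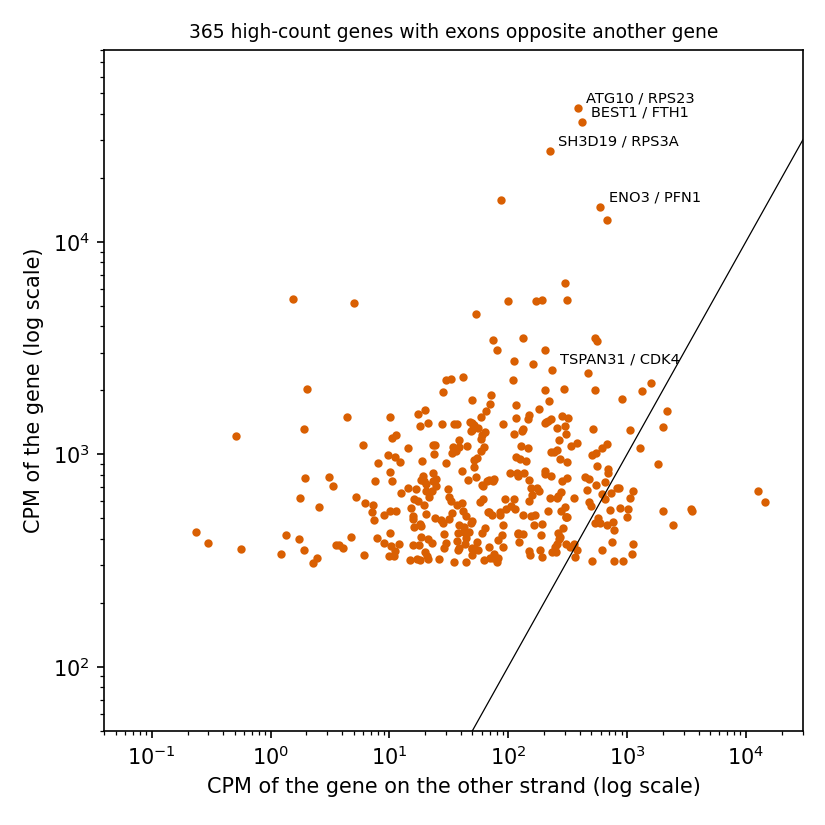
CPM of 365 high-count genes with exons opposite another gene (vertical axis) against CPM of that other gene (horizontal axis), both on log scales, means of 12 libraries; each point is a gene and the diagonal marks equality. Only 37 of the 365 opposite genes hold at least as many counts.

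CUDC-907 against control asked what 10 h of an inhibitor of histone deacetylases (HDACs) and PI3K does to mRNA levels. Of 7870 genes, 2022 rose and 1828 fell (adjusted p < 0.05), of which 1609 and 1382 changed at least 2-fold. DESeq2 called 2074 and 1693, and limma-voom 2011 and 1853. The balance turned with the scaling: scaled on genes clear of opposite-strand exons, 1801 rose and 2080 fell. Genes with 0 counts in control led the rise. RASD2 (ENSG00000100302, chromosome 22, 35936915 to 35950048), a small GTPase gene, went from 0 to 279 counts over 3 libraries, at least 78.5-fold. By the same bound HPCA (a neuronal calcium sensor, opposite TMEM54) rose at least 76.0-fold, ALPK2 (an alpha kinase, opposite AC105105.1) at least 67.0-fold and IFI6 (an interferon-induced gene) at least 65.9-fold. RGMA, a guidance molecule, rose at least 48.4-fold, CREB3L3, a liver transcription factor, at least 45.3-fold, and CLU, a secreted chaperone, at least 36.3-fold. C6orf201 (opposite ECI2) rose at least 36.0-fold, EXTL1, a glycosyltransferase, at least 28.1-fold, and TAT, tyrosine aminotransferase (opposite TAT-AS1), at least 27.3-fold.

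Among the falling genes, HK2 (ENSG00000159399, chromosome 2, 75059782 to 75120486), the inducible hexokinase, went from 158 CPM (SD 24.4) to 1.87 (SD 1.66), with a log2 fold change of -6.30 (SE 0.39, adjusted p = 3.6e-18). It lies opposite AC019069.1. DDX21, a nucleolar helicase, fell by 5.13 log2 units (SE 0.47, adjusted p = 1.1e-11) from 94.4 to 2.34 CPM, and TRPM2, a cation channel, by 5.0 (SE 0.53) from 41.1 to 1.13 CPM. C1orf204 (ENSG00000188004, chromosome 1), which lies opposite SLAMF8, fell by 4.97 (SE 0.27, adjusted p = 5.6e-17) from 596 to 19.3 CPM. TSACC, a kinase co-chaperone, fell by 4.90 (SE 0.50), and IMPAD1, a phosphatase, by 4.39 (SE 0.65). ANAPC10, a ubiquitin ligase subunit opposite ABCE1, fell by 4.41 (SE 0.34) from 202 to 9.63 CPM. CEND1, a neuronal cell-cycle gene, was 39.7 times lower (95% counting interval 10.6 to 334), HPDL, a dioxygenase, 31.6 times lower (10.4 to 156), and RABL3 (a GTPase, opposite GTF2E1) 25.3 times lower (8.27 to 126).

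Counts of several named regulators and drug targets changed, under the strand limit given above. Own-strand counts of the 53 pairs also rose with CUDC-907, from 2.26% to 3.75% of opposite-strand counts. Small rises, such as those of HDAC1 and BAX, were not separated from that shift. MYC (ENSG00000136997, chromosome 8, 128747680 to 128753674) fell by 3.71 log2 units (SE 0.26, adjusted p = 1.7e-16) from 206 CPM (SD 19) to 15.7 (SD 2.24). BCL2 (ENSG00000171791, chromosome 18, 60790579 to 60987361), the target of venetoclax, rose by 2.20 (SE 0.28, adjusted p = 8.1e-09) from 22.5 CPM (SD 1.37) to 104 (SD 10.4). MCL1, a pro-survival gene of the BCL-2 family, did not pass (log2 fold change -0.70, SE 0.35, adjusted p = 0.0952). It did pass without CUDC-907 replicate 3 (0.0290) and when scaled on clear genes (0.0433). CHEK1, a checkpoint kinase (ENSG00000149554, chromosome 11), rose by 3.12 (SE 0.32, adjusted p = 1.7e-11), and CDKN1A, a cell-cycle inhibitor opposite DINOL, by 2.08 (SE 0.25). PIK3CD, the PI3K delta catalytic subunit opposite CLSTN1, rose by 2.0 (SE 0.21, adjusted p = 1.1e-10). HDAC1 rose by 0.81 (SE 0.20, adjusted p = 6.4e-04) and HDAC2, opposite HDAC2-AS2, fell by 1.04 (SE 0.23, adjusted p = 1.9e-04).

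Of the other named regulators, MEIS1, a leukemia homeobox gene opposite MEIS1-AS2, rose by 1.37 (SE 0.36, adjusted p = 0.0015). BCL2L11, which encodes the pro-apoptotic BIM and lies opposite MIR4435-2HG, rose by 1.72 (SE 0.54, adjusted p = 0.0069), a call lost without control replicate 3 (0.0519) or CUDC-907 replicate 3 (0.144). BAX, a pore-forming gene, rose by 0.72 (SE 0.24, adjusted p = 0.0128), lost without control replicate 1 (0.0904) or CUDC-907 replicate 3 (0.0610). HDAC3, opposite AC008781.1, rose by 1.02 (SE 0.35, adjusted p = 0.0146), lost without control replicate 1 (0.0784) or CUDC-907 replicate 3 (0.127). HDAC6 (0.93, adjusted p = 0.0873), PIK3CB (0.89, 0.354), BBC3 (0.53, 0.192), HOXA9 (0.13, 0.753), FLT3 (0.02, 0.974) and WEE1 (-1.09, 0.173) did not pass. PMAIP1, PIK3CG, HDAC10, PIK3CA, BCL2L1, BAK1 and BCL2A1 were too low to test, with at most 11 counts in any library.

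**Figure D3:**
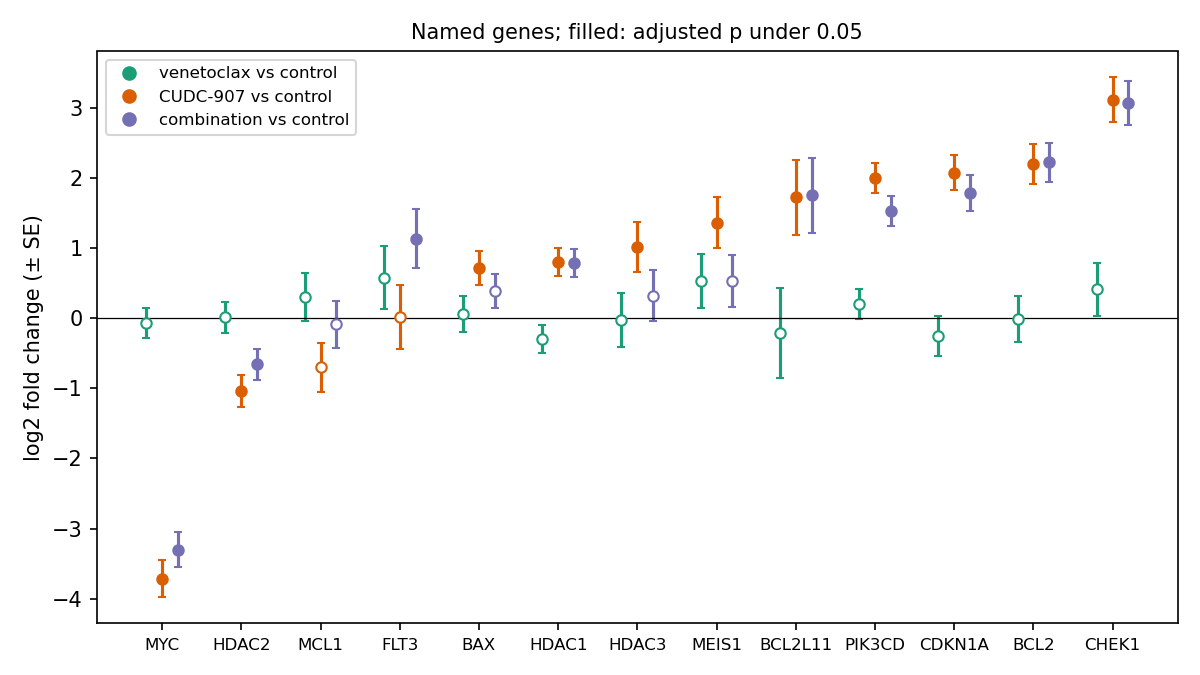
Log2 fold change and SE of 13 named genes in venetoclax, CUDC-907 and the combination, each against control, n = 3 libraries per group; filled points passed adjusted p < 0.05. MYC lies at -3.71 and BCL2 at 2.20 after CUDC-907, and no gene passed after venetoclax.

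With CUDC-907, 7 of the 33 lists moved, and fry called 20. Only the HDAC inhibitor-induced genes held with an estimated correlation, here (adjusted p = 0.0466) and in the combination against control (0.0470). All 9 tested HDAC inhibitor-induced genes rose (median log2 fold change 3.66, adjusted p = 5.0e-05), among them MT2A, a metallothionein (4.49, SE 0.41), and H1F0, the linker histone H1.0 (4.28, SE 0.37). Of 30 MYC target genes, 19 fell and 2 rose (median -1.29, adjusted p = 2.5e-05), with WDR43 (-3.84, SE 0.46), NOLC1 (-3.51, SE 0.34) and RRS1 (-3.19, SE 0.27), 3 ribosome-assembly genes, lowest after DDX21. That call had adjusted p = 0.222 with an estimated correlation. Of 41 cytosolic ribosomal proteins 38 rose and 0 fell (median 0.86, adjusted p = 2.2e-12), including RPL38 (1.26, SE 0.19, opposite MGC16275) and RPLP1 (1.20, SE 0.18), with adjusted p = 0.361 with an estimated correlation. Of 25 lysosome and autophagy genes 13 rose and 0 fell (median 0.89, adjusted p = 0.0010), led by CTSF and the sialidase gene NEU1 (2.69, SE 0.38), with adjusted p = 0.0703 with an estimated correlation. Adjusted over the list alone, the counts of these 4 lists were the same, as they were for every list given below without such a count.

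The other 3 lists that moved were the interferon, lymphoid and neuronal lists. All 5 interferon response genes rose (median 2.56, adjusted p = 0.0055), with ISG15, a ubiquitin-like modifier opposite AL645608.3, up 2.56 (SE 0.61), and adjusted p = 0.148 with an estimated correlation. Of 7 lymphoid markers 6 rose and 1 fell (median 2.46, adjusted p = 0.0422). GNLY, a cytotoxic granule gene, went from 1 to 170 counts, 143 times higher (95% counting interval 25.4 to 5702), and PRF1, which encodes perforin, was 59.9 times higher (10.4 to 2401). All 4 neuronal genes rose (median 4.18, or 3.26 with bounds, adjusted p = 0.0438), with CHGB, a granin, at least 12.9-fold and VGF, a neuropeptide gene, at 2.83 (SE 0.49). With an estimated correlation, adjusted p was 0.196 for both the lymphoid markers and the neuronal genes. The lymphoid call was lost without control replicate 1 (0.0762), control replicate 2 (0.0579) or combination replicate 3 (0.0701), and the neuronal call without the same libraries (0.0685, 0.0583 and 0.0634) and with library totals (0.0538).

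None of the metabolic lists passed with camera. Complex I genes (31 tested, 8 rose, 2 fell, median 0.24, adjusted p = 0.475) included NDUFB9 at 1.24 (SE 0.20, opposite MTSS1 and TATDN1) and NDUFB2 at -1.06 (SE 0.27, opposite BRAF). TATDN1 held 5253 CPM and NDUFB9 173. In complexes II to V, 14 of 39 rose and 4 fell (median 0.48, adjusted p = 0.121), with the ATP synthase genes ATP5H at 2.34 (SE 0.30, opposite KCTD2) and ATP5F1 at -1.99 (SE 0.19, opposite WDR77). Of 5 mitochondrial DNA-encoded mRNAs 2 rose (median 0.30, adjusted p = 0.495; adjusted over the list alone, 3 rose and 1 fell), MT-ND2 (0.54, SE 0.14) and MT-CO3 (0.36, SE 0.13, adjusted p = 0.0199). The MT-CO3 call was lost without control replicate 1 (0.0618), 2 (0.0504) or 3 (0.0930), without CUDC-907 replicate 1 (0.0754) or 2 (0.0842), and when scaled on clear genes (0.220). The TCA cycle list (9 of 25 rose, 5 fell, median 0.21, adjusted p = 0.759) held PDK2, a pyruvate dehydrogenase kinase (3.90, opposite SAMD14), and PC, pyruvate carboxylase, which fell from 996 to 134 CPM (-2.89, opposite LRFN4). Glycolysis (6 of 22 rose, 4 fell, median 0.06, adjusted p = 0.722) held HK1 at 2.87 (SE 0.39, opposite RPS15AP28) beside the loss of HK2. Fatty acid oxidation (5 of 15 rose, 1 fell, median 0.05, adjusted p = 0.475) held ACADS, a dehydrogenase gene, at 1.95 (SE 0.44). When scaled on clear genes the medians of glycolysis and fatty acid oxidation turned negative (-0.07 and -0.08). Cholesterol synthesis (5 of 17 rose, 2 fell, median 0.20, adjusted p = 0.722) held MVK, mevalonate kinase, at -1.46 (SE 0.21, opposite MMAB). Nucleotide and one-carbon synthesis (2 of 20 rose, 7 fell, median -0.70, adjusted p = 0.164) held the purine gene PFAS at -4.12 (SE 0.48) and the pyrimidine gene CAD at -2.47 (SE 0.34).

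Growth and stress lists did not pass either. PI3K and AKT components (3 of 13 rose, 5 fell, median -0.17, adjusted p = 0.925) held the phosphatase INPP5D at 1.68 (SE 0.19) and AKT1 at -1.81 (SE 0.32, opposite AL583722.2). FOXO target genes (5 of 13 rose, 3 fell, median 0.15, adjusted p = 0.800) held KLF2 at 2.44 (SE 0.57), and HDAC genes (5 of 9 rose, 1 fell, median 0.94, adjusted p = 0.135) held HDAC7 at 1.68 (SE 0.28, opposite AC004466.1). In the ATF4 and integrated stress response list 3 of 15 rose and 8 fell (median -1.04, adjusted p = 0.0977), with the amino acid transporter SLC7A1 at -2.78 (SE 0.41) and the stress gene DDIT4 at 1.67 (SE 0.40, opposite DDIT4-AS1). Of 13 heat shock genes 2 rose and 6 fell (median -0.39, adjusted p = 0.121), and HSPH1, a chaperone, went from 174 to 11.4 CPM (-3.91, SE 0.30). Mitochondrial ribosomal proteins (4 of 40 rose, 11 fell, median -0.32, adjusted p = 0.203) held MRPS34 at -1.91 (SE 0.22).

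None of the cell-cycle and death lists passed with camera. Of 25 G1/S genes 1 rose and 6 fell (adjusted over the list alone, 1 and 4), with a median of -0.61 and adjusted p = 0.095, which became 0.0362 without CUDC-907 replicate 3. The replication helicase genes MCM4 (-1.76, SE 0.25) and MCM2 (-1.51, SE 0.19, opposite AC023593.1) led that fall. Of 22 G2/M genes 5 rose and 1 fell (median 0.37, adjusted p = 0.504), with the spindle gene TPX2 at 1.06 (SE 0.25) and the cyclin CCNA2 at -0.63 (SE 0.18, opposite EXOSC9). DNA damage checkpoint and repair (2 of 22 rose, 4 fell, median -0.22, adjusted p = 0.674) held XRCC3 at 1.39 (SE 0.17, opposite KLC1), and p53 target genes (6 of 15 rose, 2 fell, median 0.60, adjusted p = 0.234) held FDXR at 1.78 (SE 0.41). Pro-apoptotic BCL-2 family genes (5 of 9 rose, 0 fell, median 0.72, adjusted p = 0.0849) held BMF at 3.52 (SE 0.53, opposite BMF-AS1) and BNIP3L at 3.46 (SE 0.44, opposite PNMA2). In the pro-survival BCL-2 family (1 of 3 rose, 1 fell, median -0.70, adjusted p = 0.925) BCL2 rose while BCL2L2, opposite PPP1R3E, fell by 1.58 (SE 0.35).

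The differentiation and signalling lists completed the set. Of 18 monocyte and granulocyte genes 6 rose and 3 fell (median 0.11, mean 1.25, adjusted p = 0.429), and the median was -0.00 when scaled on clear genes. The integrin ITGAM rose from 3.89 to 71.3 CPM (4.14, SE 0.39) while SPI1, a myeloid transcription factor, fell by 1.5 (SE 0.23). KMT2A-fusion target genes (5 of 16 rose, 2 fell, median 0.45, adjusted p = 0.475) held HOXA7 at 2.26 (SE 0.53, opposite HOXA-AS3) and the kinase CDK6 at -1.43 (SE 0.25, opposite AC002454.1). Immediate early and ERK response genes (5 of 11 rose, 3 fell; adjusted over the list alone, 6 and 3; median 1.00, adjusted p = 0.722) held IER3 at 4.51 (SE 0.40, opposite IER3-AS1). For NF-kB and inflammatory genes (2 of 6 rose, 1 fell, adjusted p = 0.879) the median was -0.47, the mean 0.31 and the test direction down, with NFKBIA at 1.84 (SE 0.47). For erythroid and megakaryocyte markers (1 of 4 rose, adjusted p = 0.755) the median was -0.34, the mean 1.10 and the test direction up, owing to the integrin ITGA2B (5.82, SE 0.53). Of 3 stromal and epithelial markers 2 rose (median 1.41, adjusted p = 0.0977), the keratins KRT18 (2.33) and KRT8 (1.41), which lie opposite each other.

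**Figure D4:**
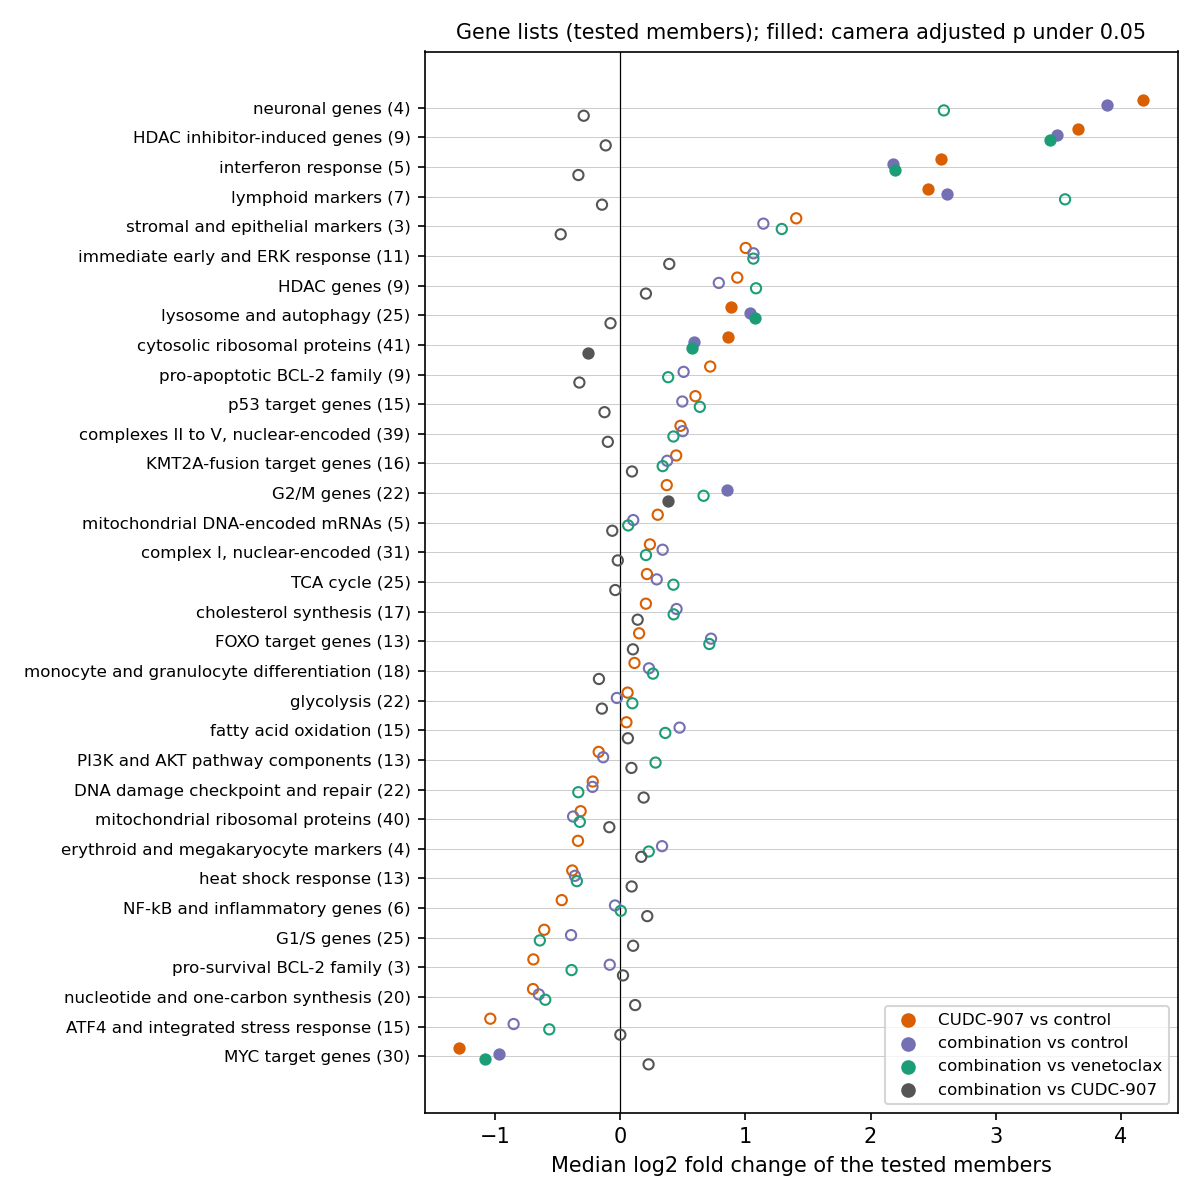
Median log2 fold change of the 33 gene lists in 4 comparisons; each point is a list, and filled points passed adjusted p < 0.05 with camera. Ribosomal proteins lie at 0.86 after CUDC-907 and at -0.26 in combination against CUDC-907, and no filled list changed sign under another scaling.

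Median shifts from the scaling were above 0.1 in some fits. Library totals moved log2 fold changes by 0.16 in combination against control, 0.17 against venetoclax, and 0.13 against CUDC-907 and in the interaction. Scaling on clear genes moved them by -0.12, -0.18 and -0.19 in CUDC-907 against control and in combination against control and venetoclax. RPLP1 and other ribosomal protein genes, MT1X and MT2A, and the keratins have close copies in the genome, so reads can be shared between them.

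Combination against control asked what both drugs do together. Here 1961 genes rose and 1621 fell, 1565 and 1137 of them at least 2-fold. DESeq2 called 1914 and 1588, and limma-voom 1973 and 1712. With library totals 2236 rose and 1346 fell, but scaled on clear genes 1611 rose and 1970 fell, so the balance turned. RASD2 rose at least 68.4-fold from 0 counts, HPCA (opposite TMEM54) at least 58.7-fold, ALPK2 (opposite AC105105.1) at least 58.0-fold and IFI6 at least 51.2-fold. RGMA followed at 48.4, C6orf201 (opposite ECI2) at 46.5, CREB3L3 at 36.8, EXTL1 at 29, CLU at 27.1 and TAT (opposite TAT-AS1) at 25.0, each as a lower bound. C1orf204, opposite SLAMF8, fell by 5.11 (SE 0.27, adjusted p = 3.0e-17). ARL10 (ENSG00000175414, chromosome 5), a GTPase gene opposite NOP16, fell by 4.28 (SE 0.18, adjusted p = 6.9e-25) to 88.6 CPM. ERCC1, a repair gene opposite CD3EAP, fell by 4.07 (SE 0.18, adjusted p = 7.8e-24). UNG, uracil DNA glycosylase, was 25.0 times lower (95% counting interval 8.09 to 125). PPP1R3G, a glycogen phosphatase subunit, fell by 4.21 (SE 0.50), TSACC by 4.20 (SE 0.45), TRPM2 by 4.15 (SE 0.47), the receptor gene TNFRSF8 by 4.04 (SE 0.61), NOXO1 (an oxidase organizer, opposite TBL3) by 4.01 (SE 0.34) and the exportin XPO4 by 4.01 (SE 0.62).

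MYC fell by 3.30 (SE 0.25, adjusted p = 1.7e-15) to 20.9 CPM (SD 7.39), and BCL2 rose by 2.22 (SE 0.28, adjusted p = 6.6e-09) to 105 CPM (SD 18.8). CHEK1 rose by 3.07 (SE 0.32), CDKN1A (opposite DINOL) by 1.79 (SE 0.25), BCL2L11 (opposite MIR4435-2HG) by 1.75 (SE 0.53), PIK3CD (opposite CLSTN1) by 1.53 (SE 0.21) and HDAC1 by 0.79 (SE 0.20). HDAC2, opposite HDAC2-AS2, fell by 0.66 (SE 0.22, adjusted p = 0.0141), lost with library totals (0.0809) or without combination replicate 2 (0.0516). FLT3, the mutated receptor kinase of this line, rose by 1.14 (SE 0.42, adjusted p = 0.0245), a call lost without control replicate 1 (0.156), control replicate 2 (0.0839) or combination replicate 3 (0.150) and when scaled on clear genes (0.0653). HDAC6 rose by 1.14 (SE 0.45, adjusted p = 0.0338), lost without control replicate 1 (0.0669), control replicate 2 (0.184), combination replicate 2 (0.181) or combination replicate 3 (0.0911), with limma-voom (0.0608) and when scaled on clear genes (0.0788). MCL1 (-0.09, adjusted p = 0.856), BAX (0.39, 0.194), MEIS1 (0.53, 0.25), PIK3CB (1.41, 0.117), HDAC3 (0.32, 0.486), HOXA9 (0.28, 0.491), BBC3 (-0.23, 0.617) and WEE1 (-0.50, 0.531) did not pass.

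With the combination 8 lists moved, and fry called 23. HDAC inhibitor-induced genes (9 of 9 rose, median 3.49, adjusted p = 5.1e-05) again included H1F0 (4.31, SE 0.36). MYC target genes (2 of 30 rose, 17 fell; adjusted over the list alone, 2 and 18; median -0.97, adjusted p = 1.2e-05) held RRS1 at -3.05 (SE 0.26), with adjusted p = 0.197 with an estimated correlation. Interferon response (5 of 5 rose, median 2.18, adjusted p = 0.0077) had adjusted p = 0.149 with an estimated correlation. Lysosome and autophagy genes (13 of 25 rose, median 1.03, adjusted p = 0.0015) held the saposin gene PSAP at 2.20 (SE 0.21), with adjusted p = 0.0818 with an estimated correlation. Ribosomal proteins (34 of 41 rose, median 0.59, adjusted p = 8.6e-07) held RPL11 at 0.99 (SE 0.17), with adjusted p = 0.534 with an estimated correlation.

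The other 3 lists passed near the bound. G2/M genes (10 of 22 rose, median 0.85, adjusted p = 0.0469) held TOP2A, topoisomerase II alpha, at 1.53 (SE 0.28) and CENPF, a kinetochore gene, at 1.27 (SE 0.29). Lymphoid markers (5 of 7 rose, 1 fell; adjusted over the list alone, 6 and 1; median 2.61, adjusted p = 0.0469) passed, and neuronal genes (4 of 4 rose, median 3.89, or 2.81 with bounds, adjusted p = 0.0469) held VGF at 2.65 (SE 0.49). Their adjusted p with an estimated correlation was 0.312 for G2/M genes and 0.197 for the lymphoid and neuronal lists. Each call was lost with library totals (0.0682). The G2/M call was lost without control replicate 1 (0.0590) or combination replicate 3 (0.122), the lymphoid call without the same libraries (0.112 and 0.0805) and the neuronal call without control replicate 1 (0.0516). Heat shock genes passed without control replicate 2 (0.0483), ATF4 and integrated stress response genes without control replicate 3 (0.0424), and mitochondrial ribosomal proteins without control replicate 2 (0.0483), control replicate 3 (0.0424) or combination replicate 2 (0.0456).

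Called genes also lay in lists that did not pass. HK2 (opposite AC019069.1) fell by 3.99 (SE 0.30) and HK1 (opposite RPS15AP28) rose by 3.07 (SE 0.38) within glycolysis (5 of 22 rose, 5 fell, adjusted p = 0.960; median -0.03, mean 0.34, test direction up, and 0.13 as the median with library totals). PC fell by 3.28 (SE 0.18, opposite LRFN4) within the TCA cycle (10 of 25 rose, 4 fell; adjusted over the list alone, 10 and 5; adjusted p = 0.695), and HSPH1 by 3.34 (SE 0.28) within heat shock genes (0 of 13 rose, 4 fell; adjusted over the list alone, 0 and 3; adjusted p = 0.117). Complex I (4 of 31 rose, 2 fell, or 3 and 1 adjusted over the list alone, adjusted p = 0.556) and complexes II to V (11 of 39 rose, 4 fell, adjusted p = 0.151) held NDUFB9 at 1.25 (SE 0.20, opposite MTSS1 and TATDN1) and ATP5F1 at -1.68 (SE 0.19, opposite WDR77). BMF rose by 3.72 (SE 0.52, opposite BMF-AS1) within the pro-apoptotic family (3 of 9 rose, adjusted p = 0.230), and BCL2L2 fell by 2.02 (SE 0.35, opposite PPP1R3E).

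Combination against venetoclax asked what CUDC-907 adds to venetoclax, with libraries that the CUDC-907 against control comparison did not use. Reading it so needs equal doses of venetoclax in both groups, and the combination doses were not stated. Of 7870 genes 1925 rose and 1669 fell, 1535 and 1174 at least 2-fold, with 1860 and 1642 called by DESeq2 and 1948 and 1739 by limma-voom. With library totals 2253 rose and 1311 fell, and scaled on clear genes 1546 rose and 1983 fell, so the balance between directions depended on the scaling. The genes that rose in both comparisons numbered 1556 (495 expected from the margins), those that fell 1346 (388 expected), and 0 and 1 genes changed in opposite directions. Fold changes correlated across genes (Pearson r = 0.888), though genes are not independent replicates. RASD2 rose at least 66.0-fold, HPCA (opposite TMEM54) 56.7, ALPK2 (opposite AC105105.1) 56.0, NGFR (a neurotrophin receptor, opposite AC015656.1) 32.1, STARD10 (a lipid transporter) 25.7 and HMOX1 (heme oxygenase 1) 25.0, each as a lower bound. SLC44A2, a choline transporter, FBXO44 (opposite FBXO2) and FAM83F (opposite Z83847.1) rose at least 21.9, 21.2 and 20.9-fold. PDGFRL, opposite MTUS1, went from 1 to 500 counts, 341 times higher (95% counting interval 61.0 to 13513).

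Falling genes again included C1orf204 (-5.14, SE 0.27, opposite SLAMF8), TRPM2 (-4.41, SE 0.46), ARL10 (-4.37, SE 0.18, opposite NOP16), FAM90A1 (-4.35, SE 0.63), XPO4 (-4.23, SE 0.62) and ERCC1 (-4.18, SE 0.18, opposite CD3EAP). PPP1R3G (-4.06, SE 0.51), TNFRSF8 (-3.90, SE 0.62) and the melanocortin cofactor MRAP (-3.88, SE 0.24, opposite URB1) followed, and UNG was 36.1 times lower (95% counting interval 11.9 to 179). MYC fell by 3.24 (SE 0.25, adjusted p = 3.4e-15) and BCL2 rose by 2.23 (SE 0.28, adjusted p = 6.7e-09). CHEK1 (2.66, SE 0.31), CDKN1A (2.04, SE 0.26, opposite DINOL), BCL2L11 (1.96, SE 0.55, opposite MIR4435-2HG), PIK3CD (1.33, SE 0.21, opposite CLSTN1) and HDAC1 (1.08, SE 0.20) rose. HDAC2, opposite HDAC2-AS2, fell by 0.67 (SE 0.22, adjusted p = 0.0128), lost with library totals (0.0731) or without venetoclax replicate 1 (0.0826). WEE1, a mitotic checkpoint kinase, did not pass (-1.32, SE 0.59, adjusted p = 0.0601) but did without venetoclax replicate 1 (0.0465), venetoclax replicate 2 (0.0413) or combination replicate 3 (0.0269), with limma-voom (0.0460) and when scaled on clear genes (0.0280). MCL1 (-0.39, adjusted p = 0.347), FLT3 (0.56, 0.265), BAX (0.33, 0.279) and MEIS1 (-0.00, 0.998) did not pass.

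Against venetoclax 5 lists moved, and fry called 22. HDAC inhibitor-induced genes (8 of 9 rose; adjusted over the list alone, 9; median 3.43, adjusted p = 1.1e-04) held MT2A at 4.77 (SE 0.46), with adjusted p = 0.0582 with an estimated correlation. MYC target genes (20 of 30 fell, 0 rose; adjusted over the list alone, 21 and 1; median -1.09, adjusted p = 8.1e-06) held NOLC1 at -2.67 (SE 0.30), with adjusted p = 0.221 with an estimated correlation. Ribosomal proteins (32 of 41 rose; adjusted over the list alone, 34; median 0.58, adjusted p = 6.7e-07) held RPLP1 at 1.00 (SE 0.18), with adjusted p = 0.499 with an estimated correlation. Lysosome and autophagy genes (12 of 25 rose, median 1.08, adjusted p = 0.0029) held PSAP at 2.56 (SE 0.22), with adjusted p = 0.103 with an estimated correlation. Interferon response genes (4 of 5 rose; adjusted over the list alone, 5; median 2.20, adjusted p = 0.0147) had adjusted p = 0.196 with an estimated correlation and 0.0637 without venetoclax replicate 1. Without venetoclax replicate 3 the count rose to 9, adding nucleotide and one-carbon synthesis (0.0485), G1/S genes (0.0485), mitochondrial ribosomal proteins (0.0146) and neuronal genes (0.0485). TOP2A (1.54, SE 0.28) rose, though the G2/M list did not pass (median 0.67, adjusted p = 0.108).

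Combination against CUDC-907 asked what 1 h of venetoclax adds to CUDC-907, provided that the unstated combination doses matched the single-drug doses. edgeR called 0 genes (lowest adjusted p = 0.0720; unadjusted p below 0.05 for 709), limma-voom called 0, and DESeq2 called 9, of which 7 were higher and 2 lower. HK2, opposite AC019069.1, was among the DESeq2 calls: it went from 1.87 CPM (SD 1.66) after CUDC-907 to 9.89 (SD 2.15) after the combination (log2 fold change 2.31, SE 0.51, adjusted p = 0.0720). MYC (0.41, SE 0.29, adjusted p = 0.693), BCL2 (0.02, SE 0.24, 0.987), MCL1 (0.61, 0.603), FLT3 (1.12, 0.363), MEIS1 (-0.84, 0.409), PIK3CD (-0.46, 0.464), CDKN1A (-0.29, 0.720) and BBC3 (-0.76, 0.471) did not pass. The count became 24 without combination replicate 2, 17 without combination replicate 1, 14 without CUDC-907 replicate 1 and 2 without CUDC-907 replicate 3. It was 39 without a low-count filter and 42 with at least 1 CPM in 3 libraries.

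By camera, 2 lists differed between the combination and CUDC-907, and fry called 0. G2/M genes were higher (median 0.38, adjusted p = 3.2e-04), with 0 members called and, adjusted over the list alone, 2 higher: TOP2A (1.01, SE 0.27) and the kinesin KIF23 (1.96, SE 0.63, opposite AC027237.3), both named after their values were seen. In other lists, adjusted over the list alone, HK2 (8.9e-04), JUNB (1.03, SE 0.32, 0.0250, opposite HOOK2) and AKT1 (1.00, SE 0.33, 0.0455, opposite AL583722.2) were higher, named here after their values were seen. Ribosomal proteins were lower (median -0.26, adjusted p = 1.9e-12), with 0 members called over all genes or over the list alone. With an estimated correlation, adjusted p was 0.418 for G2/M genes and 0.794 for ribosomal proteins. Complex I (median -0.02, adjusted p = 0.699) and complexes II to V (median -0.10, adjusted p = 0.744) did not pass. Mitochondrial DNA-encoded mRNAs passed only without CUDC-907 replicate 3 (0.0253).

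Venetoclax against control asked what 1 h of BCL-2 inhibition does alone. edgeR, DESeq2 and limma-voom each called 0 genes (lowest edgeR adjusted p = 0.867; unadjusted p below 0.05 for 293). MYC (-0.07, SE 0.21), BCL2 (-0.01, SE 0.32), MCL1 (0.31, SE 0.34), BCL2L11 (-0.21), BBC3 (-0.14), BAX (0.06), CHEK1 (0.41), FLT3 (0.58) and MEIS1 (0.53) all had adjusted p of 1. Without venetoclax replicate 3 edgeR called 1 gene, NUDT22, a nucleotide hydrolase with opposite-strand exons (-2.15, adjusted p = 0.0011), named after its value was seen, and the same gene passed without a low-count filter (2.85e-04) and with at least 1 CPM in 3 libraries (2.09e-04). No list moved by camera (lowest adjusted p = 0.920; unadjusted p below 0.05 for 0) or fry. Ribosomal proteins had a median of -0.02 but passed as lower without venetoclax replicate 1 (0.0093) and as higher without venetoclax replicate 3 (8.0e-05). In simulated data 15 of 50 genes changed 2-fold were recovered here, so changes of that size could have been missed.

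The interaction asked whether venetoclax changed genes differently after CUDC-907 than without it, again provided that the doses matched. edgeR, DESeq2 and limma-voom each called 0 genes (lowest edgeR adjusted p = 0.261; unadjusted p below 0.05 for 511). HK2, opposite AC019069.1, had the lowest p (2.60, SE 0.57, adjusted p = 0.261). Adjusted over their lists alone, HK2 (7.3e-04), JUNB (1.73, SE 0.43, 0.0021, opposite HOOK2) and the tRNA exportin XPOT (2.0, SE 0.63, 0.0404) passed, named here after their values were seen. MEIS1 (-1.37, SE 0.51, adjusted p = 0.731), PIK3CD (-0.67, 0.749), MYC (0.48, SE 0.36, 0.836), FLT3 (0.54, 0.885), MCL1 (0.31, 0.918) and BCL2 (0.03, 0.996) did not pass, so the FLT3 call with the combination but not with CUDC-907 was no tested difference. Without venetoclax replicate 3 the count was 5 and without CUDC-907 replicate 1 it was 1. With no low-count filter it was 3, and with at least 1 CPM in 3 libraries it was 5, HK2 included in both. Of the lists, ribosomal proteins were lower than the sum of the single-drug changes (median -0.28, adjusted p = 2.9e-07), with 0 members called over all genes or over the list alone. That call was lost without venetoclax replicate 1 (0.0574), had adjusted p = 0.802 with an estimated correlation, and fry called 0 lists.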

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

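The label of 1 of the tests below, on genes opposite ribosomal protein genes, was settled after its value was seen. The cytosolic ribosomal protein list was marked because camera with the preset correlation called it in the interaction of the 2 drugs (adjusted p = 2.9e-07). That call was lost with an estimated correlation (0.802), and fry called 0 lists. After CUDC-907 alone the list stood 0.86 log2 units above control and after the combination 0.59, while RPL38 lay at 1.26 and 1.05 and RPL32 at 1.20 in CUDC-907 against control. Per library, the list's median log2 level above the control mean was 0.56, 0.83 and 0.35 in the combination and 0.88, 0.80 and 0.99 after CUDC-907, so combination replicate 3 held the lowest value. The interaction call was also lost without venetoclax replicate 1 (0.0574), and 0 members passed alone.

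The rise of the list with CUDC-907 was weighed against scaling and against leakage of reads from the other strand. The other scalings tried did not remove the rise: the lowest median was 0.74, above the bound of 0.3. Those scalings moved log2 fold changes in this comparison by medians of only 0.05, 0.03 and -0.12. Shifts of that size could not bring the list to the bound, so a larger scaling error was not excluded. A larger share of reads from the other strand in treated libraries might also raise the list, because own-to-opposite percent rose from 2.26 (SD 0.234) in control to 3.75 (SD 0.165). Genes lying opposite a ribosomal protein gene had a median of -0.11 over 10 genes, which met the bound of under 0.2 for that cause. Because only 2 of the 10 held more counts than their ribosomal protein gene, the test was set as undecided after that was seen, and a count with the stated strand setting would settle it.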

How the results depend on the processing

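Some of the tests here, those on genes clear of opposite-strand exons, scaling on those genes, library totals for the lists and the fits without combination replicate 3 in comparisons that do not use it, were chosen after the results were seen. No called result for a named gene turned direction in a refit. CUDC-907 against control and combination against control and venetoclax kept their counts of called genes within 1.5 times under every planned setting, the 2-fold bound included, with 2991, 2702 and 2709 genes. Of 441 called results for named genes, 57 of 3939 refits lost the call (30 results), and leaving out a library lost it in 165 of 2646 (68 results). Of 78 uncalled results, 3 of 676 refits (2 results) and 5 of 576 with a library left out (3 results) passed. The limits are 3 libraries per group, no stated culture structure, strand setting or combination doses, and lists whose calls rest on a preset correlation. Where a value moved, the cause was not tested.

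Library totals lowered the lists moved in combination against control to 5. Without a low-count filter 1 gene was called with venetoclax (NUDT22), 39 in combination against CUDC-907, and 3 in the interaction (ACOT13, FAM92A1 and HK2). With at least 1 CPM in 3 libraries the counts were 1 (NUDT22), 42 and 5 (ACOT13, FAM92A1, HK2, ZCWPW1 and DEK). DESeq2 called 9 in combination against CUDC-907. These genes, outside the naming rule, were named after their values were seen. Camera with an estimated correlation left 1 list in CUDC-907 against control, 1 in combination against control, and 0 in combination against CUDC-907, combination against venetoclax and the interaction. Fry called 20, 23, 0, 22 and 0 in the same order. Only genes clear of opposite-strand exons gave 1577 called genes with CUDC-907, 1456 and 1436 with the combination against control and venetoclax, and 3 against CUDC-907 (YWHAG, IMPAD1 and DEK), a smaller number by construction because 3729 genes are clear. There 4 lists were higher and 3 lower with CUDC-907, and 5 and 4, and 4 and 5, with the combination against control and venetoclax. Lower lists were gained in all 3, and the interferon and neuronal lists, with 2 clear members each, were not tested. The pseudocount alternative did not apply to counts and was not run.

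Samples share only a replicate number, so the block was a check. Across 18 pairs of libraries with the same number, correlations of residuals ran from -0.0904 to 0.159, and 4 were over 0.1. The libraries that correlated best with their own number in all other groups numbered 0. With the replicate block 30 genes were called in combination against CUDC-907 (29 higher, 1 lower) and 7 in the interaction, all higher. The G2/M and lymphoid lists lost their call in combination against control (0.0512 and 0.0539). It moved no other count of calls by over 1.5 times.

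Leaving out each library in turn gave 0 to 1 genes and 0 to 1 lists with venetoclax, 3455 to 4060 genes and 5 to 8 lists with CUDC-907, and 3155 to 3623 genes and 5 to 10 lists with the combination against control. The lowest list count, 5, came without control replicate 1. Combination against CUDC-907 gave 0 to 24 genes and 2 to 3 lists, with G2/M adjusted p from 1.2e-04 to 0.0186 and ribosomal protein adjusted p from 4.2e-20 to 1.8e-06. Combination against venetoclax gave 3172 to 3527 genes and 4 to 9 lists, with 9 without venetoclax replicate 3. The interaction gave 0 to 5 genes (5 without venetoclax replicate 3, 1 without CUDC-907 replicate 1) and 0 to 1 lists (0 without venetoclax replicate 1).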

Other observations

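Several of the tests in this part, on ribosomal protein pairs, mitochondrial mRNAs, widely expressed genes, counting without regard to strand and genes opposite MYC targets, were chosen after the results were seen. Some genes opposite listed genes changed with CUDC-907. BEST1, outside the naming rule and named after its value was seen, lies opposite the ferritin gene FTH1 and rose by 1.97 log2 units (SE 0.14, adjusted p = 1.1e-16) from 16368 to 64263 CPM. Of 6 genes opposite a MYC target gene 4 fell and 1 rose. ARL10, opposite NOP16, fell by 4.05 (SE 0.18), GLT8D1, opposite GNL3, by 2.27 (SE 0.22), TSPAN31, opposite CDK4, by 1.95 (SE 0.15) and COG8, opposite NIP7, by 0.48 (SE 0.18), while EMC1, opposite MRTO4, rose by 1.16 (SE 0.29) and HIGD2A did not pass (-0.21). Of 8 genes opposite a nucleotide synthesis gene 6 fell and 0 rose (median -1.51). In other sets, 4 of 6 opposite a DNA damage gene fell, 3 of 8 opposite a G1/S gene fell and 2 of 3 opposite an ATF4 list gene fell, with 0 rising, and 3 of 3 opposite a fatty acid oxidation gene rose. Some sets went both ways: 7 fell and 4 rose of 15 opposite a mitochondrial ribosomal protein gene, 6 and 2 of 11 opposite a TCA cycle gene, 3 and 3 of 12 opposite a complex I gene, and 2 and 4 of 7 opposite a PI3K pathway gene. Opposite a cytosolic ribosomal protein gene 4 fell and 1 rose of 10, although 38 of 41 members of that list rose. Opposite a gene of complexes II to V 5 fell and 2 rose of 11, although 14 of 39 members rose and 4 fell. The rest were 1 and 2 of 4 opposite a FOXO target gene, 1 and 1 of 5 opposite a G2/M gene, 2 and 1 of 6 opposite a p53 target gene and 1 and 2 of 6 opposite a lysosome gene. No set was tested as a group.

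A hypothesis is that counts of such genes are the mRNA of the gene on the other strand. The genes opposite MYC targets prompted it, so their median of -1.21 does not test it. The MYC target held fewer counts in 4 of the 6 pairs. Sets opposite cytosolic ribosomal protein, complexes II to V, TCA cycle, PI3K and p53 genes moved against the balance of their lists. Those opposite nucleotide synthesis, mitochondrial ribosomal protein, G1/S, DNA damage, ATF4, fatty acid oxidation, FOXO and lysosome genes moved with it. Neither decides the question, because under the hypothesis the counts of list members would not be their own mRNA. Counting the reads again with each strand setting would test it.

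For the excess of high counts in genes with opposite-strand exons, counting without regard to strand was excluded: reads of the opposite gene's mRNA would leave that gene at least as many counts, and only 10.1% of 365 did, with a median of 9.81% of the gene's CPM (quartiles 3.22% and 31.7%). Clear ribosomal protein genes had 34.3 times the median CPM of genes opposite a ribosomal protein gene, which met that cause's bound of 0.5 but would also hold with reads counted on the right strand. Counting on the opposite strand could explain the pattern but was left undecided by 4 tests. Only 23.1% of 13 ribosomal protein genes held fewer counts than the gene opposite, which met the bound against it. Some of those pairs share few bases, such as 11 for RPL35 and WDR38, so the opposite gene could hold few such reads either way. MT-ND6 held 41.4% to 48.4% of mitochondrial mRNA counts, between bounds of 10% and 50%, which were set after the results were seen. Fold changes of 341 pairs correlated across genes at 0.417, between bounds of 0.3 and 0.6, and 55.6% of 36 widely expressed genes held fewer counts, between 25% and 75%. Genes are not independent replicates, and 8 mitochondrial mRNAs at 0 to 2 counts stayed unexplained.

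More genes with counts after CUDC-907 were weighed against depth, a few dominant genes and reads from the other strand. The lowest treated library held 869 more genes than the highest other library. With all libraries thinned to the smallest total the gap was 856 (SD 33.0, 20 draws), and without the 100 most abundant genes it was 976 (SD 21.6). With clear genes thinned to a single own-to-opposite ratio it was 527 (SD 43.0). Depth and a few dominant genes were excluded by the bound of no overlap. The third test also met that bound, but it left genes with opposite-strand exons as they were. Reads from the other strand are therefore not excluded, and the gap was smaller there than as deposited. Whether the wider set of genes reflects transcription at loci undetected in control, such as those of RASD2 and HPCA (opposite TMEM54), was not tested.

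Splits of the same libraries into 3 against 3, of which there are 10, were too few for a share under 0.05. For called genes the real value and the highest other were 0 and 0 for venetoclax, 3850 and 0 for CUDC-907, 3582 and 0 for the combination against control, 0 and 2 against CUDC-907, and 3594 and 0 against venetoclax, and 10, 1, 1, 10 and 1 splits reached the real value. For lists they were 0 and 5, 7 and 7, 8 and 7, 2 and 2, and 5 and 8, and 10, 2, 1, 5 and 4 splits reached the real value. For the interaction, 100 of 100 drawn splits reached the real 0 genes, with up to 1953 in another split, and 83 reached the real 1 list, with up to 9. Splits of the other comparisons and of the interaction mix libraries with and without CUDC-907, a structure of the samples. Those of venetoclax against control and of combination against CUDC-907 do not. Camera called 1, 1, 2, 2, 1, 1, 5, 0 and 0 lists in the other splits of venetoclax against control. In those of combination against CUDC-907 it called 2, 2, 2, 1, 2, 0, 0, 1 and 0. Camera with the preset correlation thus called lists in many splits that did not separate the treatments. In combination against CUDC-907, 5 of 10 splits, the real one included, reached the real 2 lists. The splits counted lists and did not follow the ribosomal protein list by itself, so they do not test it.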
